A study of Rattus norvegicus with 15 samples.

How the data were processed

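Gene expression was measured in aortas of Sprague Dawley rats on one-colour Agilent arrays, with 15 arrays in 5 groups of 3. Per the labels' protocols, total RNA was prepared with a TriZol-based kit, and the RNA of 2 rats of one group was pooled for each sample. Labelled cRNA was made with Cy3 and the Agilent Low-Input Quick Amp kit. The groups were sham rats and 5/6 nephrectomized (NX) rats given vehicle, paricalcitol at 0.08 µg/kg, alfacalcidol at 0.04 µg/kg or VS-105 at 0.01 µg/kg, injected 3 times a week for 12 days. The submitters' processing notes name Partek 6.0. Background correction, scaling between arrays and the choice of features kept are not given in the sources used here.

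The authors' deposited table of values holds 15739 features on a log2 scale, with 1 row per gene symbol or other identifier. The log2 scale was checked against the authors' deposited fold changes: group means of the values gave each listed fold change within 0.0005 (log2). The authors' deposited comparison sheets give an unadjusted p-value for each group against sham from an ANOVA whose terms are not given in the sources used here. Beside each p-value, the deposited sheets give a signed fold change, a ratio at or above 1 or minus its inverse. Array medians lay between 2.33 and 2.64, and the lowest value of an array between -5.88 and -2.71, so small values of one array can lie below the lowest value of another. All value columns were assigned to a group from the sample labels, with 0 left unmapped. Cyp24a1 is not in the table and was not analysed here.

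Feature names were matched to a rat gene table: 9187 matched a current symbol, 1555 an older synonym and 23 more than 1 gene, and 4974 had no match. A usable gene symbol was available for 10726 features, and 16 symbols were held by more than 1 feature. Current symbols are printed, so that Bmal1 stands for the older Arntl.

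Group means were fitted to all 15 arrays with limma 3.58.1 (lmFit and eBayes at their defaults) in R 4.3.3. The fit had 10 residual degrees of freedom, a prior variance of 0.0502 and prior degrees of freedom of 2.62. From it 10 comparisons were taken: NX-vehicle against sham, each compound against NX-vehicle, each pair of compounds, and each compound against sham. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all features within a comparison. A feature passed at an adjusted p under 0.05, and the moderated F test over the 5 groups used the same threshold. These p-values measure the spread between pools of 2 rats, and the number of arrays limits the precision. A change is a difference of group means on the log2 scale, with the standard error of the fit, and a level is a mean ± SD over 3 arrays.

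The groups, comparisons, tests, gene lists, the rule for the genes named and the alternative settings planned were fixed before the data were examined. The rule named, per comparison, the 8 largest rises and the 8 largest falls (5 and 5 between compounds) among features that passed, had a gene symbol and had all 3 arrays of one group on one side of all 3 of the other. Where fewer than 4 features passed, it named the 4 features with a gene symbol and the smallest p. From each gene list it named up to 3 members that passed, or the 2 with the smallest p where none did. The genes looked up in each comparison against NX-vehicle or sham included Vdr, Nos3, Edn1, Spp1, Mgp, Acta2, Col1a1 and Ccl2. Some genes that these rules select are not reported here. Any gene named outside this rule is stated to have been chosen after its values were seen.

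38 gene lists, for pathways and for cell types that an aorta with attached tissue could hold, were tested with limma's camera at its preset correlation of 0.01, adjusted over the 38 lists within a comparison. Camera with a correlation estimated from the residuals, and fry, were run beside it. None of the 38 lists was called with an estimated correlation in any of the 10 comparisons, and each camera or fry call in the report has that p beside it. Counts of list members past the threshold are given over all features and, where useful, adjusted over the list alone. Lists for platelets, intestinal epithelium and exocrine pancreas were added after the data had been examined. Overlaps and correlations of changes between comparisons that share the vehicle arrays were set beside 100 simulations of unchanged groups with the same shared arrays.

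The pipeline was tested on simulated data in which 50 of 15739 features carried a change of each size. For NX-vehicle against sham, 7 of 50 features changed by 0.5 (log2) were recovered, 28 of 50 changed by 1, 45 of 50 changed by 2 and 48 of 50 changed by 3. For NX-VS-105 against NX-vehicle the recovered counts were 3, 25, 46 and 46. A changed gene list was called in 10 of 10 simulated comparisons, and 0 of 370 unchanged lists were called by camera. The simulated features varied independently and the lists were drawn at random. These counts therefore do not cover real lists, whose genes can vary together.

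Arrays of NX-vehicle and paricalcitol with the same number deviated together from their group means in all 3 pairs (r = 0.622, 0.516 and 0.264), which pairs them by their values, since the labels give no shared batch or day. No other 2 groups had all 3 pairs over 0.1. There were 16 alternatives on the counts of features, apart from leaving out each of the 15 arrays in turn. Planned ones were quantile normalization, subtraction of array medians, leaving out the features with the lowest means (11804 kept), 1 value per symbol, eBayes with trend, robust eBayes, array weights by the gene-by-gene method (the REML method stopped before it converged), fits to the 6 arrays of a comparison alone, a replicate block, a plain ANOVA at an unadjusted p under 0.01 with a 2-fold change, a plain ANOVA with adjusted p, and an added 2-fold threshold. Chosen after seeing the data were a paired fit of paricalcitol against NX-vehicle, a common floor at the highest array minimum, a fit without NX-vehicle arrays 2 and 3, and the mean of the white adipocyte list as a covariate. Figures were drawn with matplotlib 3.10.9, and tables were handled with pandas 2.3.3 in Python 3.11.15. The deposited sheets not used hold subsets of the sheet of all listed genes with the same values.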

Results

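The data are aortic expression profiles of 15 samples: 3 from sham rats and 3 from each of 4 groups of rats made uremic by removal of 5/6 of kidney tissue (NX). NX rats received vehicle or 1 of 3 vitamin D receptor agonists, paricalcitol, alfacalcidol or VS-105, over 12 days. Each sample is a pool of RNA from 2 rats. The doses of the compounds differed (0.08, 0.04 and 0.01 µg/kg), so a difference between compounds is also a difference in dose. Values are log2 signals of 15739 features per array, with array medians from 2.33 to 2.64. Over the 5 groups, 970 features passed the moderated F test. The plot of calls per comparison shows how these spread over the 10 comparisons. Features whose 3 arrays of one group all lay on one side of the 3 of the other made up 10.6% in NX-vehicle against sham and 36.9% in NX-VS-105 against sham, where chance gives 10%.

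Some arrays carried transcripts of other tissues. Genes of a list for intestinal epithelium, made after the values were seen, had a mean of 0.42 on NX-vehicle array 2 and 2.92 on NX-vehicle array 3, against -2.39 to -0.66 on the other 13 arrays. Skeletal muscle genes had a mean of 3.92 on NX-VS-105 array 1, against -0.11 to 1.04 on the others. White adipocyte genes ranged from 2.94 (NX-vehicle array 2) to 5.93 (NX-VS-105 array 3). The plot of tissue lists gives these means for each array.

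**Figure D1:**
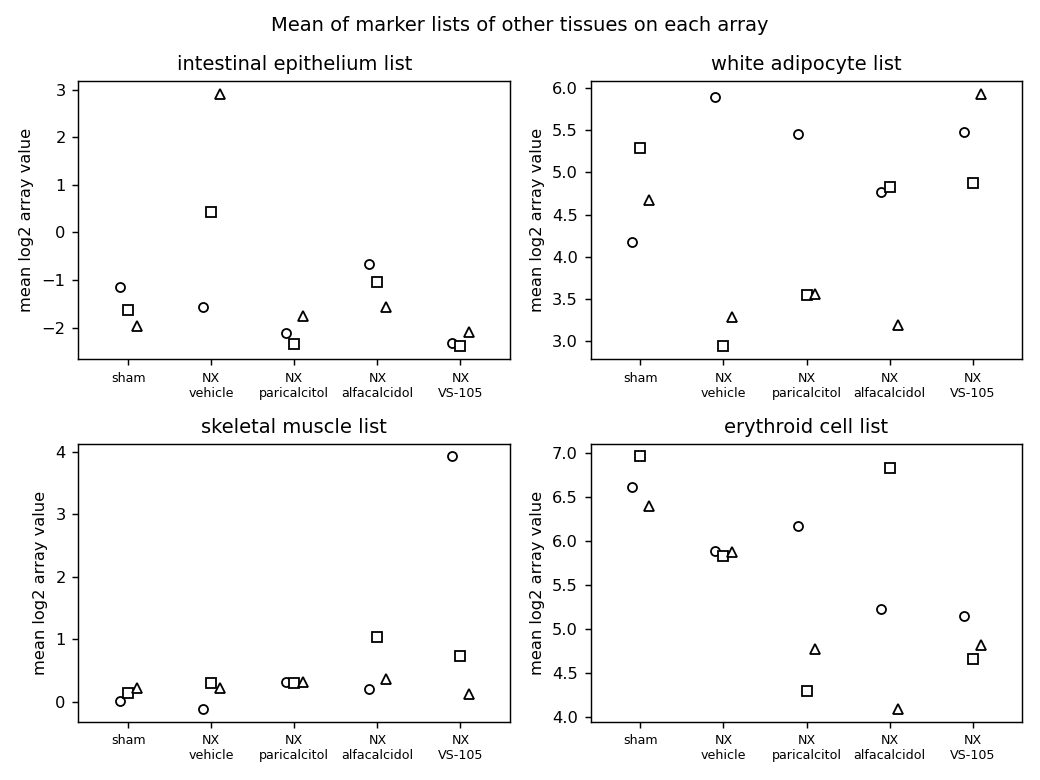
Mean log2 signal of the genes of 4 tissue lists on each of the 15 arrays, by group, with circle, square and triangle for arrays 1, 2 and 3. The intestinal list stands at 2.92 on NX-vehicle array 3 and 0.42 on array 2, and the skeletal muscle list at 3.92 on NX-VS-105 array 1.

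**Figure D2:**
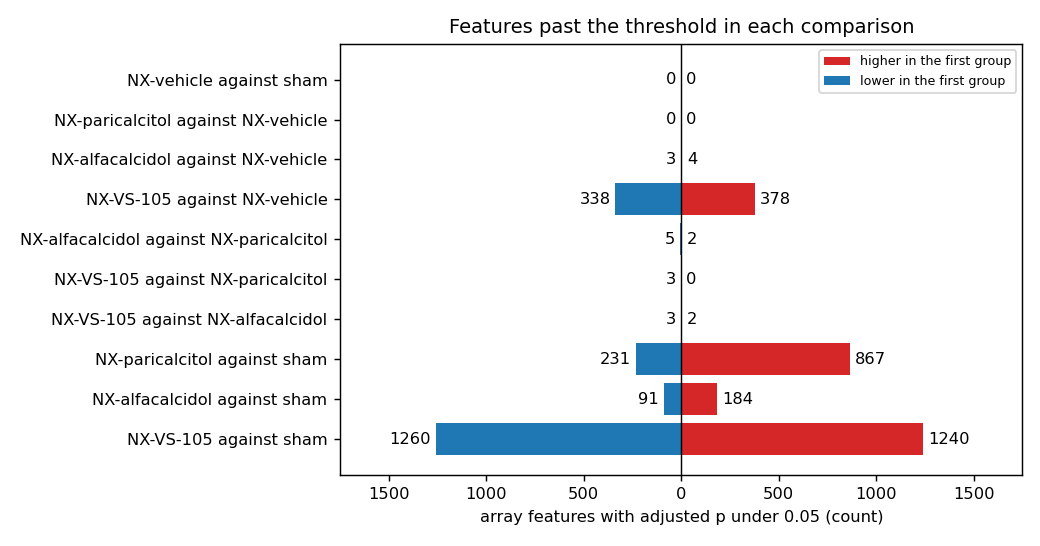
Number of features with an adjusted p under 0.05 in each of the 10 comparisons, with features higher in the first group as red bars to the right and lower ones as blue bars to the left. NX-VS-105 against sham has the most calls (1240 higher, 1260 lower), and NX-vehicle against sham and NX-paricalcitol against NX-vehicle have 0.

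NX-vehicle against sham asks what uremia did to the aorta. The labels give no injection schedule for sham rats, so vehicle injection may differ here along with nephrectomy. Changes were of modest size against the spread between pools, and no single gene passed the test. The smallest p-values of features with a gene symbol belonged to a pair of platelet glycoproteins with lower levels in NX-vehicle and a chaperone with a higher one. Gp1bb, a subunit of the platelet receptor for von Willebrand factor, was at 2.59 ± 0.07 against 3.55 ± 0.25 (mean ± SD, n = 3 each, log2), a change of -0.96 (adjusted p = 0.0798). Gp9, of the same receptor, was at 0.24 ± 0.29 against 1.38 ± 0.23, a change of -1.14 (adjusted p = 0.0798). Dnaja1, a co-chaperone of heat shock protein 70, was at 5.29 ± 0.15 against 4.28 ± 0.14, a change of 1.01 (adjusted p = 0.0798). Ezh2, a histone methyltransferase, differed by 0.83 (adjusted p = 0.146).

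Macrophage genes had the smallest camera p of the 38 lists in that comparison, with a mean change of 0.59 over 16 genes (camera adjusted p = 1.32e-08, and adjusted p = 0.463 with an estimated correlation). None of the 16 passed over all features, and 11 were higher adjusted over the list alone, among them Adgre1, the F4/80 antigen, at 0.99 (adjusted p = 0.409) and C1qc, a chain of complement C1q, at 0.88 (adjusted p = 0.438). Cell cycle genes had a mean change of 0.74 (camera adjusted p = 2.90e-07, and adjusted p = 0.463 with an estimated correlation), with Top2a, a DNA topoisomerase, at 2.15 (adjusted p = 0.380) and Cdk1, the mitotic kinase, at 1.82 (adjusted p = 0.438). Of 20 cell cycle genes, 0 passed over all features and 3 were higher adjusted over the list alone. Complement and coagulation genes had a mean of 0.53 (camera adjusted p = 6.65e-07, and adjusted p = 0.463 with an estimated correlation). Immediate early genes had one of 0.95 (camera adjusted p = 1.61e-05, and adjusted p = 0.463 with an estimated correlation), and contractile smooth muscle genes one of -0.22 (camera adjusted p = 0.0168, and adjusted p = 0.651 with an estimated correlation). Intestinal genes, high on NX-vehicle arrays 2 and 3, had a mean change of 2.17 over 27 genes (camera adjusted p = 4.48e-12, and adjusted p = 0.0877 with an estimated correlation). These 2 p-values are adjusted over the 3 added lists alone. Edn1, which encodes the vasoconstrictor endothelin-1, was at -0.25 ± 0.36 against -1.21 ± 0.27 with an adjusted p of 0.380. Changes of other genes central to vessel biology were 0.15 (adjusted p = 0.873) for Nos3, endothelial nitric oxide synthase, 0.02 (adjusted p = 0.990) for Vdr, the vitamin D receptor, 0.89 (adjusted p = 0.556) for Ccl2, a monocyte chemoattractant, and -0.52 (adjusted p = 0.514) for Acta2, smooth muscle actin. Limma called 0 features, with 1423 at an unadjusted p under 0.05, and the same test without moderation called 0. Leaving out sham array 3 gave 2 calls, and array weights gave 10.

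The authors' deposited table lists 89 genes for NX-vehicle against sham, 68 higher and 21 lower, of which 86 met an unadjusted p under 0.01 and a 2-fold change. All 89 had the same direction here, and 0 passed the adjusted threshold. In the authors' deposited table for all 3 compounds, 23 genes are higher in NX-vehicle than in sham with no p under 0.01 for any compound against sham. Of these 23 genes in the authors' deposited table, 12 were on the intestinal list. The authors chose these lists on the same arrays, so the shared direction is not independent evidence.

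Paricalcitol against NX-vehicle asks what this agonist, at 0.08 µg/kg, changed in uremic aorta. No single gene passed. The 4 smallest p-values of features with a gene symbol belonged to genes with lower signals under paricalcitol, all 4 of a group of 23 features that followed Pax3 across the 15 arrays (r above 0.9). Pkib, an inhibitor of protein kinase A, was at 2.36 ± 0.19 against 3.58 ± 0.31, a change of -1.21 (adjusted p = 0.0657). Next were Tcf15, a bHLH transcription factor, at -0.78 (adjusted p = 0.0657), Pax3, a paired box transcription factor, at -0.76 (adjusted p = 0.0715), and Hrh4, a histamine receptor, at -0.90 (adjusted p = 0.0715). Vdr was at -0.59 ± 0.68 against 0.60 ± 0.27, a change of -1.19 (adjusted p = 0.259).

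Immediate early genes had a mean change of -0.98 over 22 genes (camera adjusted p = 4.00e-11, and adjusted p = 0.416 with an estimated correlation). Fos was at -3.09 (adjusted p = 0.338) and Egr1 at -1.69 (adjusted p = 0.335), both transcription factors induced within minutes of a stimulus. Cell cycle genes had a mean change of 0.90 (camera adjusted p = 1.54e-07, and adjusted p = 0.416 with an estimated correlation). Of these 20 genes 0 passed over all features and 11 were higher adjusted over the list alone, such as Plk1, a mitotic kinase, at 1.14 (adjusted p = 0.259) and Ube2c, a ubiquitin-conjugating enzyme of mitosis, at 1.15 (adjusted p = 0.259). Genes of mesothelium and epithelium had a mean change of -1.37 (camera adjusted p = 1.20e-06, and adjusted p = 0.174 with an estimated correlation). Its smallest p-values were those of Cldn3 at -3.52 (adjusted p = 0.259) and Epcam at -3.21 (adjusted p = 0.259), epithelial genes that were high on the NX-vehicle arrays with intestinal transcripts. The intestinal list itself differed by -2.66 (adjusted p = 0.0152 with an estimated correlation, over the 3 added lists alone). Endothelial vasoactive genes had a mean of -0.04 and a median of 0.02, while camera gave them a downward call against the other genes (camera adjusted p = 0.0347, and adjusted p = 0.416 with an estimated correlation). Nos3 differed by -0.43 (adjusted p = 0.433), Edn1 by 0.04 (adjusted p = 0.938) and Spp1, osteopontin, by 1.42 (adjusted p = 0.399). Limma called 0 features, with 2325 at an unadjusted p under 0.05, the same test without moderation called 8, and subtracting array medians gave 14, all lower. With arrays of the same number in these 2 groups as pairs, 0 passed, with 4923 at an unadjusted p under 0.05. Camera then no longer called the endothelial vasoactive genes (adjusted p = 0.0572). The pairs were chosen because these arrays deviated together, which lowers the spread left in the fit, so 4923 is not comparable with 2325. The median of all features was 0.15 higher under paricalcitol. Leaving out NX-vehicle array 1 gave 22 calls, and leaving out NX-alfacalcidol array 2 gave 1.

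Under alfacalcidol, a vitamin D prodrug given at 0.04 µg/kg, genes of the circadian clock changed against NX-vehicle. Ciart, a repressor of the clock, rose from -2.11 ± 1.17 to 1.67 ± 0.40 (n = 3 each, log2), a change of 3.78 (adjusted p = 0.0148), which was 3.54 with lower values raised to a common floor, the highest array minimum. Per2, a core clock repressor, rose by 1.79 (adjusted p = 0.0157), and Wee1, a mitosis-inhibiting kinase under clock control, by 1.39 (adjusted p = 0.0217). Bmal1, the activator at the centre of the clock, fell from 1.95 ± 0.64 to -0.65 ± 0.28, a change of -2.59 (adjusted p = 0.0148). Also past the threshold were Ifrd2 at 0.87 (adjusted p = 0.0314) and Mest, an imprinted gene, at -1.45 (adjusted p = 0.0225).

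Of 17 clock genes, 3 passed over all features, 2 higher and 1 lower, and adjusted over the list alone 10 were higher and 4 lower. Camera did not call the clock list (adjusted p = 0.118), whose members move both ways, and fry called it (adjusted p = 0.0138), while the adjusted p was 0.429 with an estimated correlation. Macrophage genes had a mean change of -0.58 (camera adjusted p = 2.77e-14, and adjusted p = 0.156 with an estimated correlation), with 0 of 16 past the threshold over all features, and 1 higher and 9 lower adjusted over the list alone. Complement and coagulation genes had a mean of -0.50 (camera adjusted p = 8.61e-12, and adjusted p = 0.111 with an estimated correlation). Fibroblast genes had one of -0.41 (camera adjusted p = 1.91e-08, and adjusted p = 0.111 with an estimated correlation). Endothelial cell genes had one of -0.38 (camera adjusted p = 5.14e-08, and adjusted p = 0.170 with an estimated correlation), and inflammatory cytokine and adhesion genes -0.45 (camera adjusted p = 3.83e-06, and adjusted p = 0.156 with an estimated correlation). Il1b, the cytokine interleukin-1 beta, differed by -1.69 (adjusted p = 0.112) and Ccl2 by -1.69 (adjusted p = 0.127). Contractile smooth muscle genes had a mean change of 0.46, with 17 of 17 positive (camera adjusted p = 0.0155, and adjusted p = 0.697 with an estimated correlation). Endothelial vasoactive genes had a mean of -0.07, a median of 0.01 and a downward camera call (camera adjusted p = 0.00357, and adjusted p = 0.186 with an estimated correlation). Vdr differed by -1.34 (adjusted p = 0.146), Nos3 by -0.80 (adjusted p = 0.209), Edn1 by -0.96 (adjusted p = 0.127) and Acta2 by 0.39 (adjusted p = 0.292). Limma called 4 features higher and 3 lower, the median of all features was 0.20 higher under alfacalcidol, and after subtracting array medians 14 were higher and 138 lower. The count was 18 without sham array 1, 11 without NX-vehicle array 2, 1 without NX-vehicle array 3, 35 without NX-paricalcitol array 3, 4 without NX-alfacalcidol array 1, 0 without NX-alfacalcidol array 2 or 3, and 14 without NX-VS-105 array 3.

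VS-105, given at 0.01 µg/kg, had the most calls of the compounds against NX-vehicle in the main fit, 378 higher and 338 lower. Clock genes changed here too. Ciart rose by 2.85 (adjusted p = 0.0129), or 2.61 with a common floor, and Dbp, a clock-controlled transcription factor, rose from 5.86 ± 0.71 to 7.58 ± 0.87 (adjusted p = 0.0478). Tef, its relative, rose by 1.32 (adjusted p = 0.0164), and Bmal1 fell from 1.95 ± 0.64 to 0.20 ± 0.31 (adjusted p = 0.0164). The vitamin D receptor gene Vdr fell from 0.60 ± 0.27 to -0.99 ± 0.16, 3.00-fold (adjusted p = 0.0281). Elovl3, a fatty acid elongase of brown fat and skin, fell by 3.58 (adjusted p = 0.0223), and Ankrd36 fell by 3.92 (adjusted p = 0.0186).

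Other rises were in Ccl21, the lymphatic chemokine, at 1.71 (adjusted p = 0.0389), Timp4, a metalloproteinase inhibitor, at 1.21 (adjusted p = 0.0245), Armc12 at 1.81 (adjusted p = 0.00572), Neu2, a sialidase, at 1.77 (adjusted p = 0.00650), and Spag1 at 2.27 (adjusted p = 0.0262). Among TGF-beta and BMP genes, Inhbb, an activin subunit, fell by 0.81 (adjusted p = 0.00650). It is one of the 23 features that followed Pax3, of which 22 passed in this comparison. Klf4, a transcription factor of vascular cells, fell by 0.86 (adjusted p = 0.0395), the 1 of 22 immediate early genes that passed, and that list had a mean change of -1.28 (camera adjusted p = 8.62e-08, and adjusted p = 0.710 with an estimated correlation). Of 15 vitamin D pathway genes, Vdr was the 1 that passed over all features, and 2 were lower adjusted over the list alone, the other being S100g, an intestinal calcium-binding protein named after its value was seen. It was at 2.83 ± 5.55 in NX-vehicle, where 2 arrays carried intestinal transcripts, and at -3.96 ± 0.60 under VS-105 (adjusted p = 0.0789). Of 17 clock genes, 5 rose and 3 fell, and 9 were higher and 4 lower adjusted over the list alone. Mitochondrial respiratory chain genes had a mean change of 0.99 (camera adjusted p = 4.02e-06, and adjusted p = 0.826 with an estimated correlation). Fatty acid oxidation genes had one of 1.08 (camera adjusted p = 0.00109, and adjusted p = 0.826 with an estimated correlation). White adipocyte genes had one of 1.39 (camera adjusted p = 0.00690, and adjusted p = 0.826 with an estimated correlation), with 0 of 15 adipocyte genes past the threshold. That list was at 4.04 ± 1.61 in NX-vehicle, whose arrays differed widely, and at 5.43 ± 0.53 under VS-105. Of the 5 groups, fatty acid oxidation genes were likewise lowest in NX-vehicle (3.52 ± 1.12) and highest under VS-105 (4.60 ± 0.35). So were respiratory chain genes, at 6.15 ± 0.77 and 7.14 ± 0.29. Whether these 2 lists followed the adipocyte content of the pools was not tested. Skeletal muscle genes had a mean change of 1.45 (camera adjusted p = 0.00536, and adjusted p = 0.826 with an estimated correlation), and 1 of 20, Myoz1, a sarcomere protein, rose by 1.52 (adjusted p = 0.0491), with muscle transcripts high on NX-VS-105 array 1.

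Large falls were in intestinal genes, which were high on NX-vehicle arrays 2 and 3. Fabp1, a fatty acid binding protein of liver and gut, fell from 0.69 ± 4.03 to -5.17 ± 0.32 (adjusted p = 0.0367), and Epcam from -1.33 ± 2.47 to -5.52 ± 0.07 (adjusted p = 0.0314). Hsd17b2, Cyp3a9, Lgals4, Cdh17 and Mep1b, all on the intestinal list, had changes of -4.69, -4.69, -4.67, -4.62 and -4.41, with an adjusted p from 0.0273 to 0.0455, and Cldn3, a tight junction gene, fell by 3.23 (adjusted p = 0.0396). Their NX-VS-105 values lay near the lowest value of the array, which differed between arrays, so the sizes of these falls have no order. With a common floor none of these 8 passed. The changes of Hsd17b2, Cyp3a9, Lgals4, Cdh17, Mep1b and Cldn3 were -2.29, -2.21, -3.04, -2.65, -2.25 and -1.46, with an adjusted p from 0.102 to 0.198. The change of Fabp1 was -3.68 (adjusted p = 0.109) and that of Epcam -1.64 (adjusted p = 0.188), and Cryba4, a crystallin with a rise of 3.22 (adjusted p = 0.0473), was at 1.73 (adjusted p = 0.111). Elovl3 and Ankrd36 remained past the threshold with it, at an adjusted p of 0.0203 and 0.0211. Of 27 intestinal genes, 8 fell over all features (adjusted p = 0.0418 with an estimated correlation for the list, over the 3 added lists alone). Nos3 differed by -0.40 (adjusted p = 0.383), Edn1 by -0.39 (adjusted p = 0.359), Ccl2 by -1.07 (adjusted p = 0.162) and Col1a1, a collagen chain, by -0.70 (adjusted p = 0.129). A fit without NX-vehicle arrays 2 and 3 leaves 1 vehicle array, so it cannot show whether the changes named here rest on them. The count was 1275 without NX-vehicle array 1, 34 without NX-vehicle array 3, and 462, 441 and 62 without NX-VS-105 arrays 1, 2 and 3. Higher features made up 52.8% of calls, and 29.0% after subtracting array medians.

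**Figure D3:**
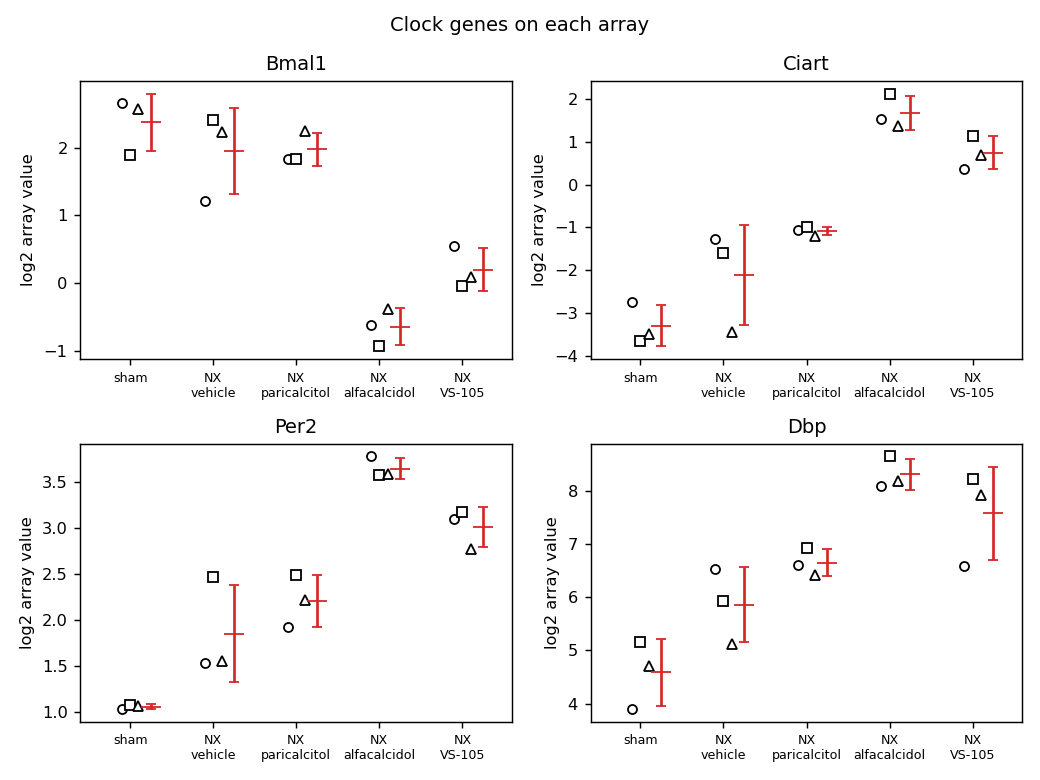
Log2 signal of the clock genes Bmal1, Ciart, Per2 and Dbp on each array by group, with circle, square and triangle for arrays 1, 2 and 3 and a red bar for the mean ± SD (n = 3). Bmal1 is at 2.37 ± 0.42 in sham and -0.65 ± 0.28 under alfacalcidol, while Per2 is at 1.06 ± 0.02 and 3.64 ± 0.11.

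Nos3, Spp1, Mgp, Acta2, Col1a1 and Ccl2 passed the test in none of the comparisons with NX-vehicle or sham, Edn1 in paricalcitol against sham, and Vdr in VS-105 against NX-vehicle and against sham. Whether the agonists acted on the same genes was asked next. Of the 7 features called for alfacalcidol and the 716 for VS-105, 6 were shared with the same direction (4 higher, 2 lower). Both changes were measured against the same vehicle arrays, and simulated unchanged groups shared no calls at this threshold, so they give no expected value. At an unadjusted p under 0.01 with a 2-fold change, 7 shared features were higher and 110 lower, where simulated unchanged groups with the same shared arrays gave 3.08 and 3.31. The shared falls are falls from vehicle arrays of which 2 carried intestinal transcripts. Ciart, Per2 and Bmal1 were among the 6. Across features, which are not independent replicates, changes of a pair of compounds from NX-vehicle correlated with r = 0.674 for paricalcitol and alfacalcidol, 0.680 for paricalcitol and VS-105, and 0.580 for alfacalcidol and VS-105, where the shared vehicle arrays alone gave 0.499, 0.502 and 0.499. These simulations take the arrays of different groups as independent, while arrays of NX-vehicle and paricalcitol with the same number correlated about their group means with r from 0.264 to 0.622. They also draw features independently, which real features are not, so they give no chance spread for the shared counts. Changes under a compound had a covariance with the change from sham to NX-vehicle of -0.0134 for paricalcitol, -0.0489 for alfacalcidol and -0.0460 for VS-105. Shared vehicle arrays alone gave -0.0604, -0.0605 and -0.0606, so the observed values were less negative than that by 0.0470, 0.0116 and 0.0146. Without the features of lowest mean (11804 kept), the covariances were 0.00892, which is of the other sign, -0.0115 and -0.0189, against -0.0318, -0.0320 and -0.0321 from shared arrays alone. The 3 vehicle arrays are too few to be divided between both changes.

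Alfacalcidol at 0.04 µg/kg and paricalcitol at 0.08 µg/kg differed in Bmal1, at -0.65 ± 0.28 against 1.97 ± 0.24 (change -2.62, adjusted p = 0.0209), and in Wee1, at 1.40 (adjusted p = 0.0298). Lower under alfacalcidol were Arsi, an arylsulfatase, at 0.90 ± 0.20 against 3.26 ± 0.43 (change -2.36, adjusted p = 0.0298), Bcl3, a regulator of NF-kappa B, at -0.95 (adjusted p = 0.0298), and Evi2a at -1.25 (adjusted p = 0.0298). Slc7a13, an amino acid transporter, was higher at 0.92 (adjusted p = 0.0473). LOC498276, named after its value was seen, differed by -1.63 (adjusted p = 0.0298). Of 17 clock genes, 1 passed over all features, and 8 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.000668, and adjusted p = 0.112 with an estimated correlation). Macrophage genes had a mean difference of -0.69 (camera adjusted p = 2.07e-20, and adjusted p = 0.112 with an estimated correlation). Inflammatory genes had one of -0.59 (camera adjusted p = 1.56e-08, and adjusted p = 0.112 with an estimated correlation). Adjusted over the list alone, 11 macrophage and 1 inflammatory genes were lower, and 0 over all features. In all, 2 features were higher and 5 lower, and the 95% interval of the difference lay within 1 (log2) of 0 for 84.0% of features. The count was 1 without sham array 3 or NX-VS-105 array 1, and 0 without any one of the NX-paricalcitol arrays or without NX-alfacalcidol array 2 or 3.

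VS-105 at 0.01 µg/kg and paricalcitol at 0.08 µg/kg differed in 3 genes, all lower under VS-105 with an adjusted p of 0.0498: Arsi at -2.36, Bcl3 at -0.93 and Entpd7, a nucleotide-hydrolysing enzyme, at -0.92 (log2 difference). Fatty acid oxidation genes had a mean difference of 0.90 (camera adjusted p = 6.59e-08, and adjusted p = 0.718 with an estimated correlation). White adipocyte genes had one of 1.24 (camera adjusted p = 4.15e-06, and adjusted p = 0.718 with an estimated correlation). Skeletal muscle genes, high on NX-VS-105 array 1, had one of 1.28 (camera adjusted p = 7.90e-06, and adjusted p = 0.718 with an estimated correlation). Collagen and elastic matrix genes had one of -0.36 (camera adjusted p = 0.00239, and adjusted p = 0.738 with an estimated correlation). Fatty acid oxidation and white adipocyte genes were both highest under VS-105 among all groups. Whether the former followed the adipocyte content of the pools was not tested. The 95% interval lay within 1 of 0 for 77.9% of features. Leaving out any one of the 15 arrays gave 0 or 1 call.

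VS-105 at 0.01 µg/kg and alfacalcidol at 0.04 µg/kg differed in Ttc36, at -2.68 ± 0.30 against 0.01 ± 0.19 (change -2.69, adjusted p = 0.0391), and Entpd7, at -1.05 (adjusted p = 0.0314). Ttc36 is one of the 23 features that followed Pax3. Features named after their values were seen were Rhox2, a homeobox gene, at 0.96 (adjusted p = 0.0388), and the unnamed transcripts FQ076898 at 2.15 (adjusted p = 0.0391) and TC638402 at -3.85 (adjusted p = 0.0314). Macrophage genes had a mean difference of 0.59 (camera adjusted p = 1.43e-09, and adjusted p = 0.564 with an estimated correlation), with 8 higher adjusted over the list alone and 0 over all features. Contractile smooth muscle genes had one of -0.47 (camera adjusted p = 0.000606, and adjusted p = 0.564 with an estimated correlation). Lists of other tissue had mean differences as well: white adipocyte genes 1.17 (camera adjusted p = 1.74e-05, and adjusted p = 0.564 with an estimated correlation), skeletal muscle genes 1.05 (camera adjusted p = 0.000119, and adjusted p = 0.564 with an estimated correlation) and lymphatic endothelium genes 0.80 (camera adjusted p = 0.00124, and adjusted p = 0.564 with an estimated correlation). Skeletal muscle genes, high on NX-VS-105 array 1, were at 1.59 ± 2.04 under VS-105 and 0.54 ± 0.44 under alfacalcidol. Per2 differed by -0.63 (adjusted p = 0.208) and Edn1 by 0.58 (adjusted p = 0.241). The median of all features differed by -0.12, and the 95% interval lay within 1 of 0 for 76.4% of features. The count of 5 became 9 without sham array 1, NX-alfacalcidol array 1 or NX-VS-105 array 2, 10 without sham array 3, 3 without NX-paricalcitol array 1 or 3, 1 without NX-alfacalcidol array 2, and 0 without sham array 2, NX-vehicle array 2, NX-alfacalcidol array 3 or NX-VS-105 array 1 or 3.

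Paricalcitol-treated uremic aorta against sham asks how far it stood from that of healthy rats. Genes of cell division rose together: Top2a from -2.89 ± 0.50 to 0.64 ± 0.75 (n = 3 each, log2; adjusted p = 0.0148) and Cdk1 from 0.11 ± 0.24 to 3.59 ± 0.77 (adjusted p = 0.0148). Of 20 cell cycle genes, 14 rose over all features and 18 were higher adjusted over the list alone, with a mean change of 1.64 (camera adjusted p = 5.20e-10, and adjusted p = 0.687 with an estimated correlation, and adjusted p = 0.0120 by fry). Trpc4, a cation channel, rose by 3.64 (adjusted p = 0.0148), and Tnnc1, a troponin of heart and slow muscle, by 4.40 (adjusted p = 0.0215). Ednra, the endothelin receptor of smooth muscle, fell from 0.98 ± 0.09 to -0.11 ± 0.24 (adjusted p = 0.0201) while its ligand gene Edn1 rose from -1.21 ± 0.27 to -0.20 ± 0.33 (adjusted p = 0.0328).

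Further large rises, all with mitotic roles, were in Nuf2 (3.78, adjusted p = 0.0201), Cdca3 (3.48, adjusted p = 0.0148) and Pbk (3.38, adjusted p = 0.0254). With a common floor the changes of Nuf2 and Pbk were 3.25 and 2.35, still past the threshold. Vtcn1, an immune checkpoint ligand, rose by 3.36 (adjusted p = 0.0243). Large falls were in Clec1b, a platelet receptor, from 2.74 ± 0.19 to 0.26 ± 0.79, and Ckm, muscle creatine kinase, at -3.17 (adjusted p = 0.0418). Others were in Trpm8, a cold-sensing channel, at -2.51 (adjusted p = 0.0220), and Cd5, a lymphocyte antigen, at -2.46 (adjusted p = 0.0454), whose change with a common floor was -1.18 (adjusted p = 0.109). Of 27 collagen and elastic matrix genes, 4 rose over all features and 7 adjusted over the list alone, including Col8a1, from 2.99 ± 0.10 to 5.15 ± 0.74, Col18a1 at 1.21 (adjusted p = 0.0327) and Postn, periostin, at 1.91 (adjusted p = 0.0471). Camera did not call that list (adjusted p = 0.0659, and adjusted p = 0.687 with an estimated correlation). Matrix proteases rose in 3 of 14 genes, and 7 adjusted over the list alone, such as Mmp2, a gelatinase, at 0.76 (adjusted p = 0.0481) and Ctsk, cathepsin K, at 1.33 (adjusted p = 0.0363). Vcam1, an adhesion molecule for leukocytes, rose from 6.78 ± 0.49 to 8.34 ± 0.89 and Icam1 by 0.87 (adjusted p = 0.0430). Of 18 oxidative stress genes, 5 rose over all features and 6 adjusted over the list alone, among them Hmox1, heme oxygenase 1, from 0.11 ± 0.18 to 1.09 ± 0.19 (camera adjusted p = 0.0473, and adjusted p = 0.687 with an estimated correlation). Of 16 macrophage genes 2 rose over all features, Adgre1 at 0.90 (adjusted p = 0.0491) and C1qc at 0.90 (adjusted p = 0.0469), and 12 were higher adjusted over the list alone (camera adjusted p = 0.000459, and adjusted p = 0.687 with an estimated correlation). Erythroid genes had a mean change of -1.58 (camera adjusted p = 0.000286, and adjusted p = 0.687 with an estimated correlation) with 0 of 6 past the threshold over all features and 6 lower adjusted over the list alone. Nr1d1, a clock repressor, rose from 1.37 ± 0.46 to 3.07 ± 0.22, 1 of 7 of the 17 clock genes that rose, and adjusted over the list alone 7 were higher and 2 lower. Hif1a, the hypoxia-inducible factor, rose by 0.93 (adjusted p = 0.0388) and Enpep, which degrades angiotensin II, by 1.71 (adjusted p = 0.0181). Vdr differed by -1.17 (adjusted p = 0.0629), Nos3 by -0.28 (adjusted p = 0.495), Spp1 by 2.26 (adjusted p = 0.0839) and Mgp, an inhibitor of calcification, by 0.68 (adjusted p = 0.139).

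In all, 867 features rose and 231 fell in this comparison, 79.0% higher, which became 54.9% after subtracting array medians, and the median of all features was 0.10 higher. Of the 56 genes in the authors' deposited table for paricalcitol, 46 passed here. In that table all 56 had an unadjusted p under 0.01 and a 2-fold change for paricalcitol against sham. For NX-vehicle against sham, 55 had such a p. The authors chose them on the same arrays, so the 46 are not independent evidence. The count was 0 without sham array 2 or NX-paricalcitol array 2, 129 without NX-paricalcitol array 3, 513 without sham array 1, 542 without NX-alfacalcidol array 3, 568 without NX-vehicle array 3, 686 without NX-VS-105 array 2 and 697 without NX-alfacalcidol array 1.

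**Figure D4:**
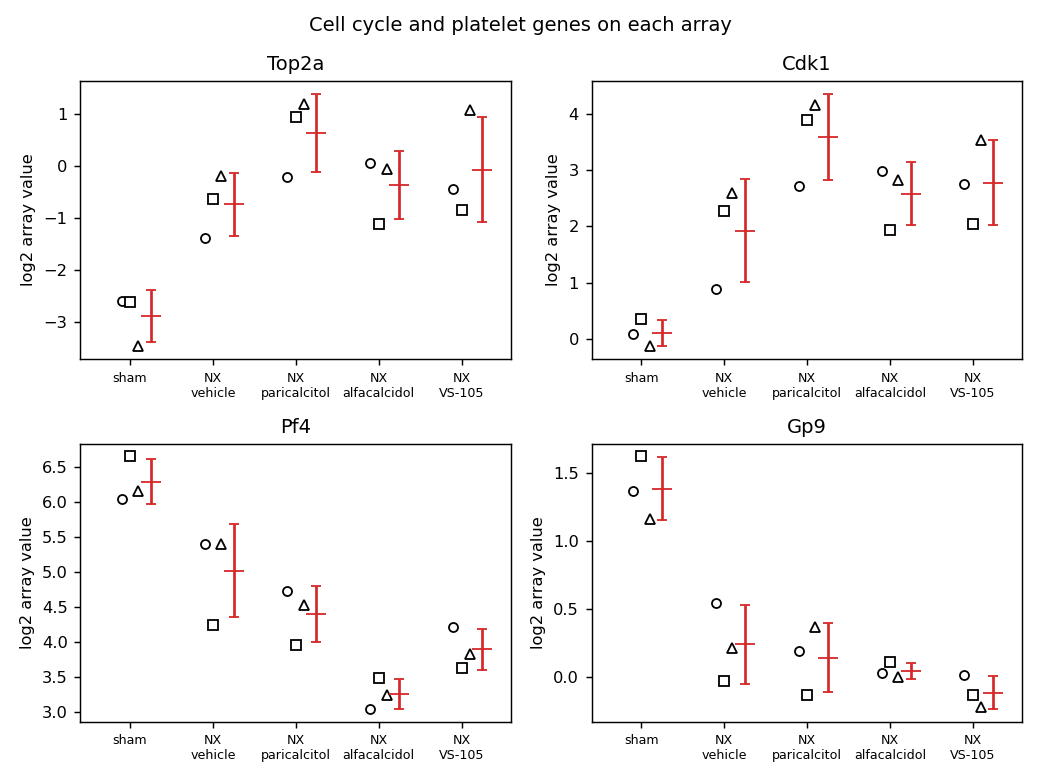
Log2 signal of the cell cycle genes Top2a and Cdk1 and the platelet genes Pf4 and Gp9 on each array by group, with circle, square and triangle for arrays 1, 2 and 3 and a red bar for the mean ± SD (n = 3). Cdk1 is at 0.11 ± 0.24 in sham and 3.59 ± 0.77 under paricalcitol, and Pf4 at 6.28 ± 0.32 in sham and 3.26 ± 0.22 under alfacalcidol.

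Alfacalcidol-treated uremic aorta against sham had its smallest p-values in genes of the circadian clock. Ciart rose from -3.30 ± 0.48 to 1.67 ± 0.40 (n = 3 each, log2), a change of 4.97 (adjusted p = 0.000702). Ciart on sham array 1, at -2.75, lay near the lowest value of that array, -3.08, and with a common floor the change was 4.39. Dbp rose from 4.59 ± 0.64 to 8.30 ± 0.30 (adjusted p = 0.00274) and Per2 from 1.06 ± 0.02 to 3.64 ± 0.11 (adjusted p = 0.000702). Bmal1 fell from 2.37 ± 0.42 to -0.65 ± 0.28 (adjusted p = 0.000718). Of 17 clock genes, 8 rose and 4 fell, and 9 were higher and 4 lower adjusted over the list alone (adjusted p = 0.000555 by fry, and adjusted p = 0.399 with an estimated correlation). Falls outside the clock list were in Pf4, platelet factor 4, from 6.28 ± 0.32 to 3.26 ± 0.22 (adjusted p = 0.000718), Clec1b at -3.25 (adjusted p = 0.00451), and S100a8 and S100a9, the subunits of calprotectin, at -3.36 (adjusted p = 0.0380) and -2.73 (adjusted p = 0.0472). With a common floor the change of S100a8 was -2.74 (adjusted p = 0.0474).

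Npy, the gene of neuropeptide Y, fell from 6.71 ± 0.27 to 3.32 ± 0.27 (adjusted p = 0.00401). Tnnc1 rose by 4.62 (adjusted p = 0.0223), Trpc4 by 3.17 (adjusted p = 0.0135) and Sphkap, an anchoring protein for protein kinase A, by 2.66 (adjusted p = 0.0234). Ednra fell by 1.19 (adjusted p = 0.0147) and Hif1a rose by 1.02 (adjusted p = 0.0476). Of 20 cell cycle genes 2 rose over all features, Cdk1 at 2.48 (adjusted p = 0.0338) and Top2a at 2.52 (adjusted p = 0.0378), and 11 were higher adjusted over the list alone (camera adjusted p = 3.40e-05, and adjusted p = 0.523 with an estimated correlation). T and NK cell genes had a mean change of -1.22 (camera adjusted p = 1.38e-08, and adjusted p = 0.295 with an estimated correlation, and adjusted p = 0.0321 by fry). Cd247, a chain of the T cell receptor complex, at -2.11 (adjusted p = 0.0400), was the 1 of 10 that fell over all features, and 7 were lower adjusted over the list alone. Il1b fell by 1.71 (adjusted p = 0.0443). Txnrd1, thioredoxin reductase, rose by 0.79 (adjusted p = 0.0326), Zbtb16, a glucocorticoid-induced transcription factor, by 2.10 (adjusted p = 0.0234), and Herpud1, of the unfolded protein response, by 1.07 (adjusted p = 0.00570). Fst, the activin-binding protein follistatin, fell by 1.41 (adjusted p = 0.0215). Endothelial cell genes had a mean change of -0.33 (camera adjusted p = 0.000101, and adjusted p = 0.399 with an estimated correlation). Vdr differed by -1.32 (adjusted p = 0.0686), Nos3 by -0.65 (adjusted p = 0.138) and Edn1 by 0.01 (adjusted p = 0.991).

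For alfacalcidol against sham 184 features rose and 91 fell, 66.9% higher, which became 40.9% after subtracting array medians, and the median of all features was 0.14 higher. Of the 46 genes in the authors' deposited table for alfacalcidol, 26 passed here. In that table all 46 had an unadjusted p under 0.01 and a 2-fold change for alfacalcidol against sham. For NX-vehicle against sham, 45 had such a p. The authors chose them on the same arrays, so the 26 are not independent evidence. The count was 31 without NX-alfacalcidol array 3, 39 without NX-alfacalcidol array 1, 861 without NX-alfacalcidol array 2, 40 without sham array 2, 146 without sham array 3 or NX-vehicle array 3, 481 without NX-vehicle array 1 and 179 without NX-VS-105 array 2.

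VS-105-treated uremic aorta against sham had the most calls of the 10 comparisons in the main fit, 1240 higher and 1260 lower. Ednra fell from 0.98 ± 0.09 to -0.43 ± 0.35 (n = 3 each, log2; adjusted p = 0.00286), and Ddah1, which clears an inhibitor of nitric oxide synthase, from 5.48 ± 0.25 to 4.02 ± 0.71 (adjusted p = 0.0159). Vdr fell from 0.58 ± 0.73 to -0.99 ± 0.16 (adjusted p = 0.0165), and Rxra, the partner receptor of Vdr, from 0.10 ± 0.44 to -1.03 ± 0.07 (adjusted p = 0.00916). Of 21 endothelial vasoactive genes 1 rose, Hif1a at 1.31 (adjusted p = 0.00775), and 3 fell, the same counts as adjusted over the list alone. Cell division genes rose, with Top2a at 2.81 (adjusted p = 0.00937) and Cdk1 at 2.67 (adjusted p = 0.00937). Of 20 genes, 11 rose over all features and 14 adjusted over the list alone (camera adjusted p = 8.75e-06, and adjusted p = 0.840 with an estimated correlation).

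Clock genes again included Ciart (4.04 (adjusted p = 0.00140), and 3.46 with a common floor), Dbp (2.99, adjusted p = 0.00398), Nr1d1 (2.24, adjusted p = 0.00140) and Tef (2.05, adjusted p = 0.00140), with 7 of 17 higher and 4 lower, and 8 and 4 adjusted over the list alone (adjusted p = 0.00340 by fry, and adjusted p = 0.840 with an estimated correlation). Kcnma1, the large-conductance calcium-activated potassium channel of smooth muscle, fell by 1.02 (adjusted p = 0.0183), while Kcna5, a voltage-gated potassium channel, rose by 1.40 (adjusted p = 0.0270), Npr3, the natriuretic peptide clearance receptor, by 1.66 (adjusted p = 0.0293) and Enpep by 1.46 (adjusted p = 0.0107). Col8a1 rose by 1.52 (adjusted p = 0.0332) and Timp4 by 1.40 (adjusted p = 0.00936), and Col1a2, a collagen I chain, fell by 0.56 (adjusted p = 0.0307). Of 16 macrophage genes 4 rose over all features, including Cd68 at 0.79 (adjusted p = 0.0259) and Folr2, a folate receptor, at 0.71 (adjusted p = 0.0244), and 9 were higher adjusted over the list alone (camera adjusted p = 0.00480, and adjusted p = 0.840 with an estimated correlation). Pecam1, an endothelial adhesion molecule, fell by 0.67 (adjusted p = 0.0446) and Actg2, a smooth muscle actin, fell by 1.10 (adjusted p = 0.0487). Of 6 erythroid genes 2 fell over all features, Ahsp at -2.49 (adjusted p = 0.0329) and Slc4a1 at -1.89 (adjusted p = 0.0435), and 6 were lower adjusted over the list alone (camera adjusted p = 0.00126, and adjusted p = 0.840 with an estimated correlation). Of 18 oxidative stress genes 4 rose, including Hmox1 at 0.75 (adjusted p = 0.0418) and Gpx3, an extracellular glutathione peroxidase, at 1.48 (adjusted p = 0.0173), and 4 adjusted over the list alone.

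Cyp2e1, a cytochrome P450, rose from 0.42 ± 0.90 to 4.94 ± 2.00 (adjusted p = 0.0154), and Myh8, a myosin of immature skeletal muscle, from -1.85 ± 0.65 to 2.58 ± 2.97 (adjusted p = 0.0333), with muscle transcripts high on NX-VS-105 array 1. Elovl3 fell by 3.52 (adjusted p = 0.0136), Ankrd36 fell by 3.45 (adjusted p = 0.0161) and Kcng3, a potassium channel subunit, fell by 3.31 (adjusted p = 0.00656). Further large falls near the lowest array values were in Or6c3, Krt85, Pcgf6l1 and Or4g7, whose sizes have no order: with a common floor the changes were -1.59, -1.20, -1.28 and -1.23, with an adjusted p of 0.241, 0.227, 0.216 and 0.215. Nos3 differed by -0.25 (adjusted p = 0.524), Edn1 by 0.58 (adjusted p = 0.107) and Acta2 by -0.54 (adjusted p = 0.0718). Of the 46 genes in the authors' deposited table for VS-105, 45 passed here. In that table all 46 had an unadjusted p under 0.01 and a 2-fold change for VS-105 against sham. For NX-vehicle against sham, 45 had such a p. The authors chose them on the same arrays, so the shared calls are not independent evidence. Higher features made up 49.6% of calls, and 37.3% after subtracting array medians. The count was 1003 without sham array 1, 1362 without sham array 2, 1408 without NX-VS-105 array 1 and 583 without NX-VS-105 array 3. In that last setting paricalcitol against sham had more calls, 987.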

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

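The tests of the clock pattern were chosen only after the result was seen, and the comparisons between compounds were planned. Because the change of each compound was measured against the same NX-vehicle arrays, a feature that differs between compounds is one whose change from NX-vehicle differs, at doses that also differ. Alfacalcidol and paricalcitol differed in this way in 7 features, led by Bmal1 and Wee1. VS-105 and paricalcitol differed in 3 features, Arsi, Bcl3 and Entpd7. VS-105 and alfacalcidol differed in 5 features, among them Entpd7 and Ttc36, which is one of the features that followed Pax3, a group for which processing of the arrays group by group stays open. With 3 arrays in each group, no array was tested as an outlier of its group.

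Clock genes stood apart between the groups, with a phase score (mean log2 value of late-phase genes minus mean log2 value of early-phase genes) of -1.71 ± 0.38 in sham, -0.65 ± 0.68 in NX-vehicle, -0.05 ± 0.26 under paricalcitol, 2.18 ± 0.30 under alfacalcidol and 1.54 ± 0.30 under VS-105 (n = 3 each). If tissue had been collected at another time of day in some groups, genes of known phase would move together, and 13 of 15 moved in the direction of their phase in NX-VS-105 against NX-vehicle, 15 in alfacalcidol and 12 in paricalcitol against NX-vehicle, and 13 in NX-vehicle against sham. The labels give no collection time, so this and an effect of treatment cannot be told apart. If the compounds alone moved the clock, NX-vehicle and sham would have equal scores, and they differed by 1.07 (exact permutation p = 0.2, two-sided, where 0.1 is the smallest possible), which leaves that open too.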

How the results depend on the processing

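The paired fit and the fits with a common floor, without NX-vehicle arrays 2 and 3 together and with the white adipocyte mean were chosen only after the results were seen, and the other settings were planned. Of 23443 values that the genes chosen by the naming rule had under other settings, 110 had a changed sign, and 0 of these passed the threshold in the main fit or in the setting. Many settings change only the test, or leave out an array of another group, so the sign could not change there. The largest rises and falls were also named for having all 3 arrays of a group on one side. The small count of changed signs is therefore no measure of robustness. The settings with a 2-fold threshold and the paired fit were not counted for single genes. Among the genes called, 8 of 26 in alfacalcidol against sham and 13 of 65 in VS-105 against sham passed in every setting counted. It was 0 of 6 in alfacalcidol against NX-vehicle, 0 of 27 in VS-105 against NX-vehicle and 0 of 45 in paricalcitol against sham. Between compounds it was 0 of 6 for alfacalcidol against paricalcitol, 0 of 3 for VS-105 against paricalcitol and 0 of 2 for VS-105 against alfacalcidol. Counts of features moved more, as given below, and unless stated the cause was not tested. Signal near the lowest values of an array limits the size of changes of weak genes, since array minima differed.

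Array weights came from the gene-by-gene method because the REML method stopped before it converged, and most of their counts lie far above those of the other settings. The weights, from 0.385 to 3.41, gave 10 features for NX-vehicle against sham, and 3107, 5996 and 3113 for paricalcitol, alfacalcidol and VS-105 against NX-vehicle. They gave 89, 35 and 108 for alfacalcidol against paricalcitol, VS-105 against paricalcitol and VS-105 against alfacalcidol. Against sham they gave 2804, 3209 and 2288 for paricalcitol, alfacalcidol and VS-105, and the F test gave 6482. With the weights alfacalcidol against NX-vehicle had the most calls of the 10 comparisons, not VS-105 against sham. Quantile normalization gave 1 for NX-vehicle against sham, 17 and 117 for paricalcitol and alfacalcidol against NX-vehicle, 11 for alfacalcidol against paricalcitol and 0 for VS-105 against paricalcitol. Subtracting array medians gave 14 and 152 for paricalcitol and alfacalcidol against NX-vehicle and 5 for VS-105 against paricalcitol. Without the features of lowest mean, the first 2 of these counts were 6 and 19, with 0 for VS-105 against alfacalcidol. With 1 value per symbol, which tests fewer features, counts were 2 and 115 for paricalcitol and VS-105 against NX-vehicle, 1 for VS-105 against alfacalcidol, 1255 for VS-105 against sham and 326 for the F test. The eBayes trend gave 1 and 19 for paricalcitol and alfacalcidol against NX-vehicle, 5 and 1 for VS-105 against paricalcitol and alfacalcidol, and 469 for alfacalcidol against sham, and robust eBayes gave 0 for VS-105 against paricalcitol.

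Fits to only 6 arrays, which use fewer samples, gave 58 and 193 for alfacalcidol and VS-105 against NX-vehicle, 0 for each pair of compounds, and 105, 169 and 502 for paricalcitol, alfacalcidol and VS-105 against sham. Arrays with the same replicate number correlated with a mean r of -0.0163 over 30 pairs, but all 3 between NX-vehicle and paricalcitol were over 0.1. A fit of these 2 groups with pairs called 0 features and 12 lists by camera, 11 of them also called without pairs, and 0 lists with an estimated correlation. A replicate block over all arrays gave 3 and 415 for alfacalcidol and VS-105 against NX-vehicle, 0 for each pair of compounds, 294 and 104 for paricalcitol and alfacalcidol against sham, and 212 for the F test. An ANOVA on each feature with adjusted p gave 8 and 0 for paricalcitol and alfacalcidol against NX-vehicle, 0 for alfacalcidol and for VS-105 against paricalcitol, 529 and 101 for paricalcitol and alfacalcidol against sham, and 263 for the F test. With an unadjusted p under 0.01 and a 2-fold change it gave 52 for NX-vehicle against sham, 60, 154 and 362 for the compounds against NX-vehicle, 48, 69 and 80 between compounds, and 437 and 636 for paricalcitol and VS-105 against sham. Adding a 2-fold threshold left 319 for VS-105 against NX-vehicle, 1 for VS-105 against paricalcitol, and 407, 161 and 749 for paricalcitol, alfacalcidol and VS-105 against sham.

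A common floor gave 17 for alfacalcidol against NX-vehicle. Without NX-vehicle arrays 2 and 3, where the lone vehicle array is assumed to vary like the other groups, counts were 2 for NX-vehicle against sham, 3 and 12 for paricalcitol and VS-105 against NX-vehicle, 1 and 0 for VS-105 against paricalcitol and alfacalcidol, and 394 for the F test. The white adipocyte covariate gave 9 for NX-vehicle against sham, 8, 1093 and 1723 for the compounds against NX-vehicle, 0 for VS-105 against alfacalcidol, 1989, 1396 and 4627 for the compounds against sham, and 3401 for the F test. Leaving out 1 array at a time, counts ran from 0 to 2 for NX-vehicle against sham, from 0 to 22, 0 to 35 and 34 to 1275 for paricalcitol, alfacalcidol and VS-105 against NX-vehicle, from 0 to 9 for alfacalcidol against paricalcitol, 0 to 1 for VS-105 against paricalcitol and 0 to 10 for VS-105 against alfacalcidol, from 0 to 1482, 31 to 861 and 583 to 2778 for paricalcitol, alfacalcidol and VS-105 against sham, and from 151 to 1275 for the F test.

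Camera with an estimated correlation called 0 of 38 lists in each of the 10 comparisons. The directional fry test called 1 list for alfacalcidol against NX-vehicle and 3 for each compound against sham, and 0 in the other 6 comparisons. The mixed fry test called 1 for NX-vehicle against sham, 0, 7 and 4 for the compounds against NX-vehicle, 3, 1 and 0 for alfacalcidol against paricalcitol, VS-105 against paricalcitol and VS-105 against alfacalcidol, and 14 and 17 for paricalcitol and VS-105 against sham. At an unadjusted p under 0.01 with a 2-fold change, 70 features were shared in direction by paricalcitol and alfacalcidol, 99 by paricalcitol and VS-105 and 117 by alfacalcidol and VS-105, where unchanged groups with shared vehicle arrays gave 5.74, 5.75 and 6.39. Shared falls were 67, 98 and 110 (simulated 2.76, 2.75 and 3.31), and shared rises 3, 1 and 7 (simulated 2.98, 3 and 3.08). Features were drawn independently in these simulations, so the chance spread of these counts is not known. Above the lowest means, the excess of the covariance of the alfacalcidol change with the NX change over the simulated value was 0.0205.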

Other observations

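The lists for platelets, intestinal epithelium and exocrine pancreas, and the tests of the intestinal genes and of the genes that follow Pax3, were chosen only after the result was seen, and the splits of the arrays were planned. The mean of the platelet list was lower in each NX group than in sham, and so were the means of other blood cell lists. From sham to NX-vehicle, paricalcitol, alfacalcidol and VS-105, the mean level (log2) of erythroid genes was 6.65, 5.86, 5.07, 5.38 and 4.87. That of T and NK cell genes was -0.11, -0.74, -0.87, -1.34 and -0.83, and that of B and plasma cell genes 1.17, 0.31, 0.42, 0.30 and 0.26. In NX-vehicle against sham, 0 of 12 platelet genes passed over all features, 6 were lower adjusted over the list alone, and 4 had a positive change. Their mean change from sham was -0.60 (adjusted p = 0.00116 with an estimated correlation). Under paricalcitol it was -0.76, with 6 genes past the threshold (adjusted p = 0.000605 with an estimated correlation), under alfacalcidol -1.13, with 5 past it (adjusted p = 3.39e-05), and under VS-105 -1.01, with 6 past it (adjusted p = 0.000503). Against NX-vehicle the mean change was -0.16 under paricalcitol (adjusted p = 0.0215), -0.53 under alfacalcidol (adjusted p = 0.000556) and -0.42 under VS-105 (adjusted p = 0.00776), with 0 genes past the threshold over all features in each. For paricalcitol fry did not call the list (adjusted p = 0.348), and 4 of the 12 genes had a positive change. Camera compares a list with the other genes, and the median of all features was 0.15 higher under paricalcitol. Alfacalcidol and paricalcitol, at different doses, differed by -0.37 (adjusted p = 0.00236). These p-values are adjusted over the 3 added lists alone, and platelet genes were seen among the smallest p-values before the list was made. The list of 4 exocrine pancreas genes passed in no comparison with an estimated correlation, and 1 of its genes fell in VS-105 against sham.

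Genes of intestinal epithelium were high in 2 of the 3 NX-vehicle samples: at least 1 (log2) above the highest sham array in 14 of 27 genes on array 2, in 22 on array 3 and in 0 on array 1. RNA of intestinal tissue in those pools would raise the whole list. The genes looked at next were those with the highest values on array 3, so their high level there is no test. Fabp1 was at 4.46 there against -0.33 on the highest sham array, and Prap1 at 5.76 against -2.76. Cdx1 and Rbp2, at 6.75 and 5.43, were below the highest sham array, 7.45 and 6.24. The count of 22 makes such RNA a candidate explanation. Of the 15 list genes that the authors' deposited table lacks, 10 were raised by that much. The list was made after these values were seen, so neither count is an independent test. Of the 27 genes, 2 are on another list and 2 had a sham mean above the median of all features. Nephrectomy raising these genes in every pool as on arrays 2 and 3 is argued against by array 1, where 0 of the 27 were raised by that much. An effect of nephrectomy in some of the rats remains open.

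Another group of 23 features, 17 with a gene symbol, followed Pax3 across the arrays with r above 0.9. They stepped between groups with a median within-group SD of 0.113, against 0.239 for all features. Pax3 itself had a within-group SD of 0.106. Features picked by their likeness to it share its small spread and its steps. The group holds Pkib, Tcf15, Pax3 and Hrh4, which had the 4 smallest p-values of features with a gene symbol in paricalcitol against NX-vehicle. Their median change from NX-vehicle was -0.71 under paricalcitol, -0.42 under alfacalcidol and -1.08 under VS-105, and NX-vehicle differed from sham by 0.09. A background signal added to the arrays of some groups would leave bright features nearly unmoved. The brighter features of this group had a median change of -1.01 in VS-105 against NX-vehicle, beside -1.20 for the dimmer ones. That argues against such a background for these picked features alone. Bright features left unmoved could hardly have been picked by their likeness to Pax3, so the medians cannot test it for other features. Processing of the arrays group by group would leave whole groups apart. In 16 of the 23 features all 3 NX-VS-105 arrays lay below every other array. That count follows in part from picking features like Pax3. The labels give no processing batch, so such processing and an effect of treatment cannot be told apart.

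Arrays of each comparison were also split in all 10 ways into 3 and 3, which are too few for a share under 0.05. The real and the highest other count of features were 0 and 1 for NX-vehicle against sham, where 10 splits gave as many, and 0 and 1 for paricalcitol against NX-vehicle (0 and 0 with pairs, over the 4 splits that part each pair), 7 and 0 for alfacalcidol, and 716 and 1 for VS-105. Between compounds they were 7 and 2 for alfacalcidol against paricalcitol, 3 and 1 for VS-105 against paricalcitol, and 5 and 0 for VS-105 against alfacalcidol. Against sham they were 1098 and 57 for paricalcitol, 275 and 1 for alfacalcidol, and 2500 and 2 for VS-105. For gene lists called by camera they were, in the same order of 10 comparisons, 22 and 16, 12 and 16, 15 and 19, 11 and 19, 16 and 16, 9 and 19, 14 and 18, 9 and 16, 11 and 20, and 7 and 18, and 1, 5, 4, 10, 2, 10, 6, 7, 5 and 10 splits gave as many. With pairs, paricalcitol against NX-vehicle had 4923 features at an unadjusted p under 0.05 in the real split. The highest count in another split was 252. The pairs were picked from the same values, and 4 splits are too few for a share under 0.05. Of 100 groupings of the 15 arrays into 5 groups, 2 gave as many features by the F test as the real 970, the real one included. The highest other count was 1318. The share of 2 in 100 is under 0.05, but it comes from few groupings and takes all arrays as exchangeable. Arrays of NX-vehicle and paricalcitol with the same number deviated together, and a replicate block gave 212 features. Chance is therefore not excluded.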
